A study of Homo sapiens with 4 samples.

How the data were processed

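Gene expression was measured on 4 Affymetrix arrays in 293HEK cells, a human embryonic kidney line, after transient transfection with ERG or with control vector. There were 2 samples per group, and groups were taken from the sample titles. The labels give no batch and no replicate numbers. They add the word duplicate to the titles of ERG 2 and vector 2, without saying whether these arrays were made together. The numbers used here (ERG 1 and 2, vector 1 and 2) therefore only name the arrays and pair none of them. The design text speaks of duplicate transfections. Whether the duplicates came from separate cultures or days is not given in the sources used here. The p-values of probe sets therefore measure the spread between these arrays, which may be technical.

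Per the labels' protocols, RNA was extracted with Trizol and treated with DNase, and biotinylated cRNA was made from 2 ug of total RNA. The deposited values are intensities on a linear scale, 1 per probe set, for 22277 probe sets. In the deposited table, the mean intensity after removal of the lowest and highest 2% of values lay between 500.11 and 500.13 in every array, which is the mark of a scaling of each array to a common target. The method that summarised probes into probe sets, its software and any background correction are not given in the sources used here. The number of arrays limits the precision of every value.

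The 62 AFFX control probe sets were left out of the tests, and the other 22215 were all tested without a filter on dim signal. Gene names came from the platform annotation: 19064 probe sets had 1 gene symbol, 1043 had several and 2108 had none. Of the probe sets with 1 symbol, 19052 were matched to a current gene record by Entrez identifier, and no symbol had to be updated. No gene was named from a probe set with several symbols. These probe sets covered 11964 genes.

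Intensities were analysed as log2(intensity + 16), a scale that understates the change of dim probe sets. By a rule set before the data were examined, quantile normalization between arrays was applied because the array medians on this scale differed by 0.25, above the limit of 0.2. The 2 groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. The fit had 2 residual degrees of freedom, and the moderation added 3.34. Errors printed with log2 differences are moderated standard errors, and each fold is on the log2(intensity + 16) scale.

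RNA quality was read from the log2 signal at the 3 prime end minus that at the 5 prime end of ACTB and GAPDH. A further control transcript is not reported here.

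The tests, the gene lists, the rule for named genes and the alternative settings were fixed before the data were examined. The 28 gene lists were the ETS family, endothelial genes, genes reported as ERG-activated in prostate cells, extracellular proteases and inhibitors, epithelial-mesenchymal transition, matrix proteins, WNT pathway, immediate early and ERK feedback genes, type I interferon response, NF-kB and inflammatory genes, cell cycle, p53 targets, unfolded protein and amino acid stress response, heat shock proteins, cholesterol biosynthesis, glycolysis and hypoxia, TGF-beta and BMP response, Notch pathway, neuronal genes, prostate epithelium markers, blood cell markers, fibroblast markers, kidney epithelium markers, replication-dependent histones, cytosolic ribosomal proteins, mitochondrial respiratory chain, amino acid solute carriers, and axon guidance and adhesion receptors. The list of ERG-activated genes was drawn up from general knowledge of earlier work and not from these samples. Of 731 list symbols, 4 matched no single gene. Lists were tested with limma's camera at a preset correlation of 0.01, on the probe set with the highest mean level of each gene, with adjustment over the lists. Camera compares the genes of a list with all other genes. At the preset correlation it tests on 11962 degrees of freedom. Its p-values then rest mainly on the spread across genes at an assumed correlation, not on the spread between arrays. It was repeated with a correlation estimated for each list, on 2 degrees of freedom.

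Named genes were to be the probe sets past the threshold with both ERG arrays on the same side of both vector arrays. Because none passed, each direction was filled to 10 genes, as the rule provides: the smallest p among probe sets above the median level, with an absolute log2 difference of at least 0.5 and the groups separated. From each list, at most 2 members with the smallest p were named when none passed the threshold. Genes named outside the rule are marked as chosen after their values were seen.

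The procedure was tested on simulated data with 22215 probe sets, of which 200 above the median level were given a known change, in a single draw per size of change. The recovery therefore says nothing of dim probe sets, and no cross-group resemblance of arrays was simulated. A log2 change of 1 or 2 was recovered in 0 of 200. A log2 change of 3 was recovered in 147 (73.5%) with 6 other probe sets called, and a change of 4 in 186 (93%) with 8 other probe sets called. With no change, nothing was called. In a single draw, a simulated shift of 0.2 in the immediate early and ERK feedback list came out at an estimated mean of 0.31 and gave a camera adjusted p of 0.00175 with 0 other lists called. The simulated probe sets vary independently, so that result holds only without correlation between genes.

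The alternatives changed the normalization, the pseudocount (1 or 64), a filter on dim probe sets, the variance model, the threshold, the probe set used per gene and the list test, and left out each array in turn. The block made of cross-group array pairs and the use of the values as deposited were added after seeing the data. For lists, a change of direction was counted from the sign of the mean log2 difference. This definition replaced camera's own direction after the results had been seen.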

Results

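The study asked how expression of ERG, a transcription factor of the ETS family, altered the transcripts of 293HEK cells. This established human line grew from embryonic kidney cells transformed with adenovirus DNA. Cells received an ERG plasmid (2 arrays) or control vector (2 arrays). The median intensity was 164 for ERG 1, 190.0 for ERG 2, 173 for vector 1 and 157 for vector 2.

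The arrays did not group by transfection. The closest pairs were ERG 2 with vector 1 (Pearson r = 0.983 across probe sets, which are not independent) and ERG 1 with vector 2 (r = 0.977). The ERG arrays correlated with each other at 0.971 and the vector arrays at 0.969. The SD of log2 differences across probe sets was 0.41 for ERG 2 with vector 1 and 0.48 for ERG 1 with vector 2. It was 0.54 within the ERG group and 0.55 within the vector group.

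**Figure D1:**
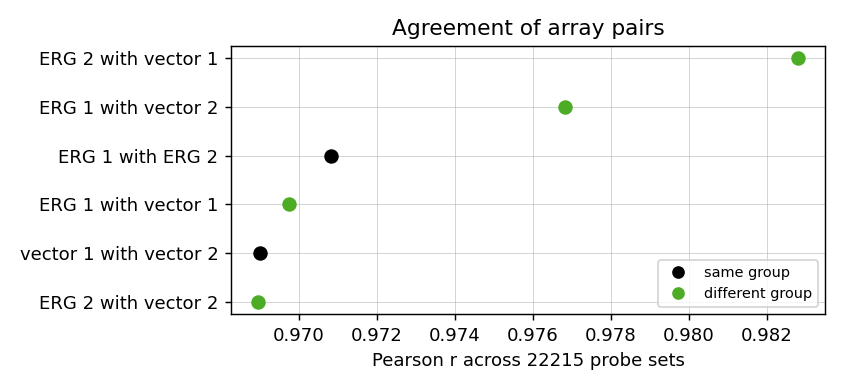
Pearson correlation across 22215 probe sets for each pair of arrays, on the normalized log2 scale, with pairs of the same group in black and pairs of different groups in green. The pairs ERG 2 with vector 1 (0.983) and ERG 1 with vector 2 (0.977) lie to the right of both same-group pairs.

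ERG itself was represented by 3 probe sets, none with a detectable difference. The brightest read 37.7 and 63.7 intensity units in the ERG arrays and 36.0 and 22.0 in the vector arrays, a log2 difference of 0.42 ± 0.29. The next read 44.9 and 32.2 with ERG and 23.5 and 42.9 with vector (0.03 ± 0.37). The dimmest read 5.26 and 7.50 with ERG and 4.13 and 4.76 with vector (0.06 ± 0.16). All 3 were dim, at the 24.4, 23.6 and 3.79 percentile of mean level, and limma's adjusted p was 0.999992 for each. Because a plasmid may carry the coding region alone and probe positions were not used here, these values do not check the labels.

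Genes with higher values in both ERG arrays than in both vector arrays included SLC2A3, which encodes a glucose transporter, and NDRG1, a gene induced by hypoxia and other stress. SLC2A3 differed by 1.27 ± 0.26 on the log2 scale, a fold of 2.42, and its other probe sets by 0.81 and 0.96. NDRG1 differed by 1.02 ± 0.21. FSCN1, the actin-bundling protein fascin, differed by 1.23 ± 0.30 and by 0.91 ± 0.23 in its second probe set. RGS2, a regulator of G protein signalling, differed by 1.12 ± 0.27, and SERPINI1, the protease inhibitor neuroserpin, by 1.28 ± 0.34. The difference for IFITM3, an interferon-induced antiviral membrane protein, was 1.67 ± 0.44, from a probe set type that can bind related transcripts. PHLDA2, an imprinted gene, differed by 1.06 ± 0.27, but by 0.10 in its other probe set. The values were 0.59 ± 0.16 for PERP, a desmosome-associated membrane protein, and 0.66 ± 0.19 for LAMP2, a lysosomal membrane protein, with 0.26 and 0.43 in its other probe sets. NR2F6, an orphan nuclear receptor, differed by 0.72 ± 0.21, and by 0.69 and 0.03 in its other probe sets.

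Genes with lower values in both ERG arrays included POLR3C, a subunit of RNA polymerase III, at -1.04 ± 0.21 and -0.61 in its second probe set. DLST, a component of the alpha-ketoglutarate dehydrogenase complex, was at -0.80 ± 0.20. DUS2, which makes dihydrouridine in tRNA, was at -1.41 ± 0.36 in its leading probe set but at -0.12 in the other. The RNA exonuclease gene REXO5 was at -1.02 ± 0.27, with -0.78 in its second probe set. The helicase-family gene RAD54L2 was at -0.93 ± 0.26, KRCC1 at -0.96 ± 0.29 and CDC42EP1, an effector of the Cdc42 GTPase, at -0.72 ± 0.22. EIF3A, a translation initiation factor subunit, was at -0.64 ± 0.20, with -0.28 and 0.02 in its other probe sets. VPS39, a subunit of a lysosomal tethering complex, was at -0.83 ± 0.26. The keratin gene KRT10 was at -0.71 ± 0.22, with -0.54 and -0.64 in its other probe sets.

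None of these genes passed the test. At an adjusted p under 0.05, limma called 0 probe sets higher and 0 lower with ERG, and the smallest adjusted p was 0.999992. At an unadjusted p under 0.05 there were 281 probe sets higher and 291 lower, 572 in all, where chance alone gives 1111. With each array centred on its 75th percentile these counts were 443 and 183, and with the values as deposited 385 and 207. With the cross-group array pairs as a block, an alternative chosen after seeing the data, they were 618 and 634. Both ERG arrays lay above both vector arrays in 2796 probe sets and below them in 2921, together 25.7% of all, against 33.3% by chance. Both chance figures assume arrays that are exchangeable. Here arrays of the same group differed more than the closest cross-group pairs, which widens the spread within groups and can lower both counts. Counts below chance are therefore no evidence that ERG changed nothing.

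**Figure D2:**
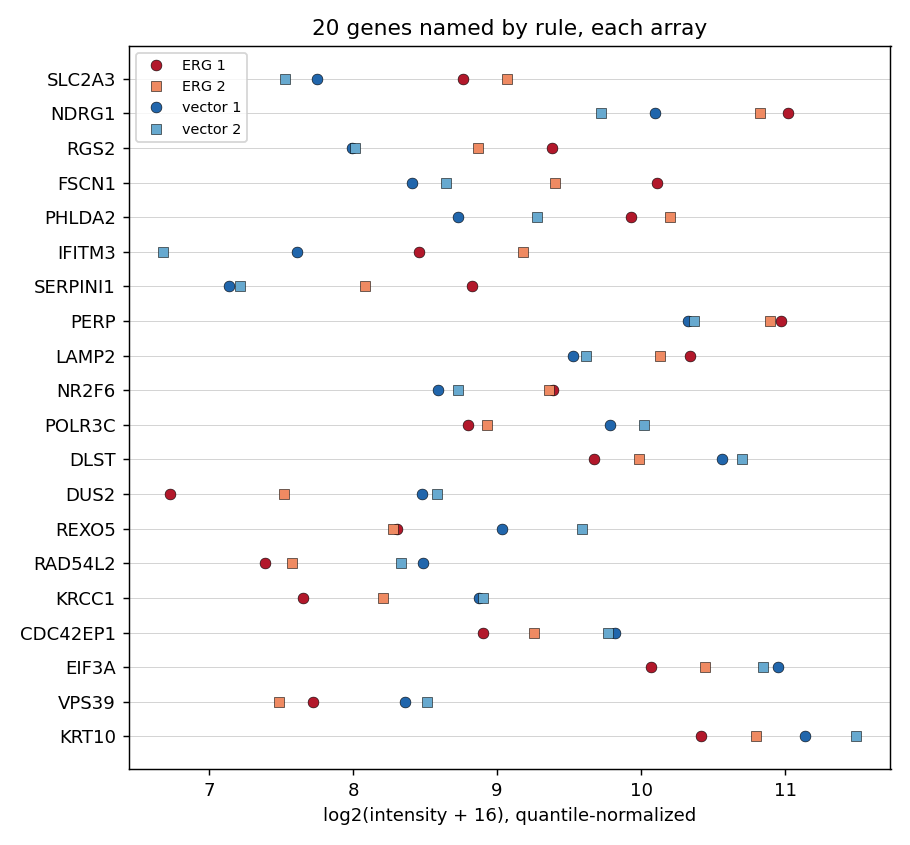
Normalized log2(intensity + 16) of the 20 genes named by rule, 1 point per array (ERG 1 and 2 in red shades, vector 1 and 2 in blue shades), with the 10 higher genes above the 10 lower ones. The groups are separated in each gene because the rule asked for it, and none passed the adjusted threshold.

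Immediate early genes and feedback inhibitors of ERK signalling were higher as a group with ERG. Of 34 measured members, 28 had higher and 6 lower values, and in 21 both ERG arrays lay above both vector arrays, with 0 the other way. The mean log2 difference was 0.36 and the median 0.27. DUSP6, a phosphatase that inactivates ERK, differed by 1.86 ± 0.37, although its other probe sets gave 1.20 and 0.13. All 3 were dim, the first at the 21.2 percentile of level, with vector values near the floor of the scale. KLF2, a zinc finger transcription factor, differed by 1.18 ± 0.38. Chosen after their values were seen, EGR1 was at 0.85 ± 0.29 (0.27 ± 0.30 in its other probe set), JUNB at 0.71 ± 0.27, IER2 at 0.48 ± 0.17 and SPRY2, an inhibitor of receptor tyrosine kinase signalling, at 0.58 ± 0.24. Camera gave an adjusted p of 5.22e-07 for the list, on 11962 degrees of freedom that come from genes and not from arrays. The call was lost in camera with a correlation estimated for the list (adjusted p = 0.642 with an estimated correlation). The estimate itself was -0.0047, under the preset 0.01, and camera then tests on 2 degrees of freedom. The list mean was higher in 4 of 4 ERG-vector array pairs, but the pairs share arrays, and 5 of the 23 lists without a call were also higher in all 4. No single member passed in limma, 0 adjusted over all probe sets and 0 adjusted over the list alone.

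Genes reported as ERG-activated in prostate cells were also higher as a group. Of 30 measured genes, 25 had higher and 5 lower values, with a mean log2 difference of 0.31 and a median of 0.27. WNT1, a secreted signalling protein, differed by 1.13 ± 0.23 and TDRD1, a germ line gene, by 0.98 ± 0.24, both at dim levels. PTGS2, the inducible prostaglandin synthase, was at 0.67 ± 0.25. The WNT receptor gene FZD4, chosen after its values were seen, was at 0.71 ± 0.30. Both ERG arrays lay above both vector arrays in 13 members and below in 1. The camera adjusted p was 4.25e-05. Camera lost this call too (adjusted p = 0.788 with an estimated correlation), the estimate being 0.037. Vector 2 lay lowest, and without it the mean was 0.19 (camera adjusted p = 0.0472, range over all alternatives 1.67e-05 to 0.788). In limma, 0 members passed adjusted over all probe sets and 0 adjusted over the list alone.

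Matrix protein genes had a mean log2 difference of 0.25, with 27 of 34 measured members higher and 7 lower. TNC, the matrix glycoprotein tenascin C, differed by 1.65 ± 0.29, but by 0.44 in its other probe set. BGN, the proteoglycan biglycan, was at -1.28 ± 0.38, with 0.06 and -0.03 in its other probe sets. The camera adjusted p was 0.0106 (adjusted p = 0.864 with an estimated correlation), and the estimate was 0.112. The camera call was lost without ERG 2, where the mean was still 0.22, and without vector 2, where it fell to 0.06. The range over all alternatives was 1.38e-04 to 0.953.

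Glycolysis and hypoxia genes had a mean log2 difference of 0.19, with 23 of 27 measured members higher and 4 lower. NDRG1 is a member, and SLC2A3 was at 0.81 ± 0.35 in the probe set used for the list. The camera adjusted p was 0.0135 (adjusted p = 0.864 with an estimated correlation), and the estimate was 0.255. The camera call was lost without ERG 1 (mean 0.10, adjusted p = 0.720), without vector 2 (mean 0.12, adjusted p = 0.106) and with each array centred on its median (adjusted p = 0.0584). The range over all alternatives was 9.09e-04 to 0.953.

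Type I interferon response genes had a mean log2 difference of 0.19, with 24 of 37 measured members higher and 13 lower. IFITM3 led the list, and IFI44L, another interferon-induced gene, was at 0.98 ± 0.29. The camera adjusted p was 0.0322 (adjusted p = 0.788 with an estimated correlation), and the estimate was -0.0063. The camera call was lost when any 1 array was left out: adjusted p = 0.0738 without ERG 1, 0.239 without ERG 2, 0.0897 without vector 1 and 0.0727 without vector 2. The range over all alternatives was 0.00131 to 0.788. In the matrix, glycolysis and interferon lists, 0 members passed limma adjusted over all probe sets and 0 adjusted over the list alone.

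**Figure D3:**
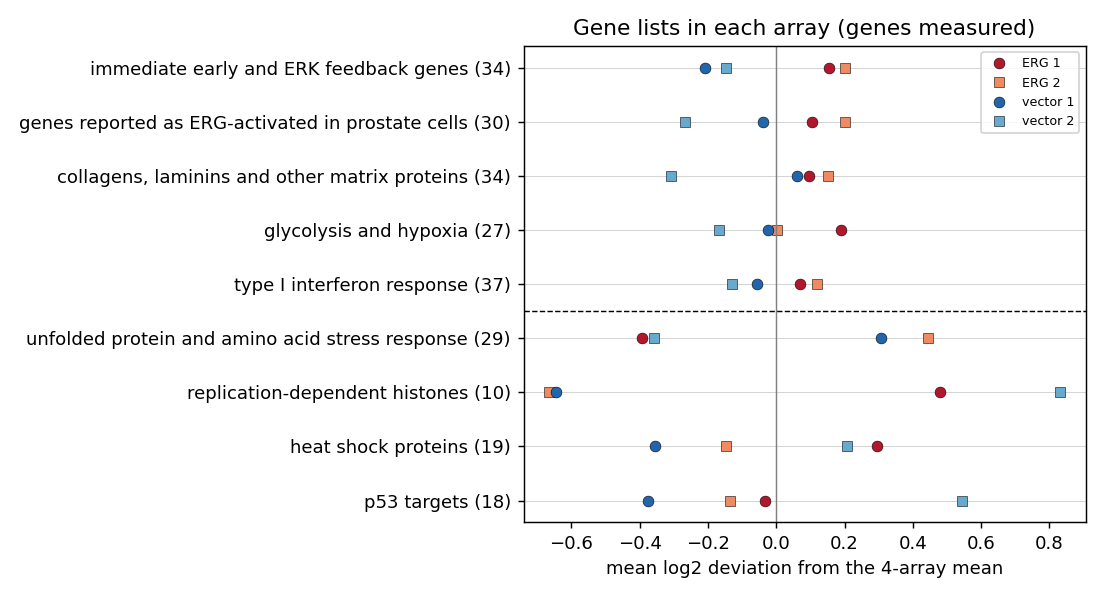
Mean log2 deviation of each array from the 4-array mean, over the measured genes of the list (their number in parentheses), with 1 point per array. The 5 lists above the dashed line had a camera adjusted p under 0.05 at the preset correlation. Below it, the stress response list reads 0.45 in ERG 2 and 0.31 in vector 1 against -0.39 in ERG 1 and -0.36 in vector 2.

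The other 23 lists did not pass in camera. Of the 54 list members named by rule, over all lists, 38 moved by over 1.5 times when 1 array was left out. The epithelial-mesenchymal transition list had a mean of 0.24 and an adjusted p of 0.0513, and leaving out 1 array gave means of 0.11 to 0.36 (camera adjusted p up to 0.631). SNAI1, a transcriptional repressor of E-cadherin, was at 1.75 ± 0.45, and CDH1, the E-cadherin gene itself, at 0.9998 ± 0.41 and 0.03 in its other probe set. The cell cycle list was at -0.07 (camera adjusted p = 0.167), with 15 of 43 members higher and 28 lower, and the replication licensing gene MCM6 was at -0.32 ± 0.19. With each array centred on its median, that list passed camera at a mean of -0.16 (adjusted p = 0.0389). The p53 target list was at -0.17 (camera adjusted p = 0.339), where the phosphatase gene PPM1D was at -0.82 ± 0.34 and the DNA repair gene DDB2 at -1.36 ± 0.60. The ETS family was at 0.10 (camera adjusted p = 0.580), with FLI1, a close relative of ERG, at 0.68 ± 0.33 and ETS1 at 0.81 ± 0.45. Leaving out 1 array gave 0.032 to 0.13 for that list, 0.37 to 1.01 for FLI1 and 0.26 to 1.34 for ETS1. Extracellular proteases and inhibitors were at 0.11 (camera adjusted p = 0.178), with MMP15 at -1.08 ± 0.35 and MMP11 at 0.58 ± 0.29. The WNT pathway was at 0.14 (camera adjusted p = 0.234), with RNF43, a ligase that removes WNT receptors, at -0.75 ± 0.29.

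Among inflammatory and signalling lists, NF-kB genes were at 0.05 (camera adjusted p = 0.522), with PTGS2 at 0.67 ± 0.25 and CXCL2, a chemokine, at 0.76 ± 0.29. TGF-beta and BMP response genes were at 0.05 (camera adjusted p = 0.710), with TGFB2 at 0.68 ± 0.41 and TGFB3 at 0.39 ± 0.31. Leaving out 1 array gave 0.20 to 1.16 for TGFB2 and 0.18 to 0.61 for TGFB3. The Notch pathway was at 0.02 (camera adjusted p = 0.909), with the ligand gene JAG1 at 0.69 ± 0.33 and LFNG at -0.77 ± 0.44, the latter from vector 2 (6.10, against at most 4.83 in the other arrays). Its median was -0.017, opposite in sign to its mean. Axon guidance and adhesion receptors were at 0.09 (camera adjusted p = 0.341), with PLXNB1 at 0.56 ± 0.32 and PLXND1 at 0.40 ± 0.26.

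Among metabolic and housekeeping lists, respiratory chain genes were at 0.10 (camera adjusted p = 0.0976), with NDUFA1, a complex I subunit, at 0.31 ± 0.16 and NDUFA2 at 0.40 ± 0.26. Heat shock proteins were at 0.15 (camera adjusted p = 0.339), with DNAJB4 at 0.35 ± 0.24. HSPA1L was at 0.98 ± 0.64, from ERG 1 alone, and leaving out 1 array gave 0.0054 to 1.93. The unfolded protein and amino acid stress response was at 0.05 (camera adjusted p = 0.422), with CRELD2 at 0.37 ± 0.16 and the chaperone gene HSPA5 at 0.47 ± 0.29. Amino acid carriers were at 0.01 (camera adjusted p = 0.810), with SLC1A5, a glutamine transporter, at 0.31 ± 0.15 and SLC7A8 at 0.28 ± 0.26. Cholesterol biosynthesis was at 0.02 (camera adjusted p = 0.817), with SQLE at 0.18 ± 0.21 and MSMO1 at 0.17 ± 0.20. The signal of ACTB at the 3 prime end minus that at the 5 prime end differed in the same way between arrays as the stress response list, at 0.59 in ERG 2 and 0.58 in vector 1 against 0.40 in ERG 1 and 0.41 in vector 2. Histone genes were at -0.19 (camera adjusted p = 0.341), with H1-2 at -0.58 ± 0.36 and H2AC25 at -0.19 ± 0.41. Ribosomal proteins were at -0.0032 (camera adjusted p = 0.974), with RPLP2 at -0.32 ± 0.28 and RPS3 at 0.09 ± 0.13. Their median was 0.013 and camera's direction was up, against a mean below 0.

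Marker lists of other cells did not pass in camera either in the main setting. Fibroblast markers passed with each array centred on its median (mean 0.26, camera adjusted p = 0.0389). Kidney epithelium markers passed above the 40th percentile of level (mean 0.31, camera adjusted p = 0.00593). Fibroblast markers were at 0.26 (camera adjusted p = 0.167), with PDGFRA at 0.95 ± 0.40 and ACTA2, smooth muscle actin, at -0.86 ± 0.39. Leaving out 1 array gave 0.11 to 0.28 for the list, 0.42 to 1.48 for PDGFRA and -1.36 to -0.35 for ACTA2. Kidney epithelium markers were at 0.14 (camera adjusted p = 0.261), with EMX2 at 0.69 ± 0.28 and CDH6 at 0.66 ± 0.35. Endothelial genes were at 0.05 (camera adjusted p = 0.710), with SOX17 at -0.49 ± 0.29 and ANGPT2 at -0.37 ± 0.25. Blood cell markers were at 0.03 (camera adjusted p = 0.677), with CD3D at 0.78 ± 0.36 and CD79A at -0.83 ± 0.58, the latter from ERG 2 (5.03, against 6.65 to 6.74 in the other arrays). Neuronal genes were at -0.09 (camera adjusted p = 0.422), with NEFH, a neurofilament gene, at -0.40 ± 0.23 and PHOX2A at -0.52 ± 0.35. Prostate epithelium markers were at 0.06 (camera adjusted p = 0.341), with the protease gene TMPRSS2 at -1.11 ± 0.33. In that list limma passed 0 members adjusted over all probe sets and 1 adjusted over the list alone, NDRG1, which other tissues also express. In the other 22 lists limma passed 0 members by either adjustment. Another probe set of the gene had the opposite sign for ANGPT2, TGFB2, JAG1, NEFH, PDGFRA, CDH6, RPLP2, SLC7A8 and PLXNB1. Of the list members named by rule, those at the 4.10 to 25.5 percentile of level were dim, so their log2 differences depend on the floor of the scale: ANGPT2, IFI44L, NEFH, HSPA1L, LFNG, TDRD1, PLXNB1, WNT1, CXCL2, MMP15, BGN, TMPRSS2, DUSP6, PDGFRA, SOX17, PTGS2, PHOX2A, CD3D and SNAI1.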

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

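The block of cross-group array pairs and the values as deposited were chosen after seeing the data. The planned floor on log2 values was not run, because the values were linear. The variance model of the robust fit was not applied to lists. The labels give no shared replicate numbers, so no pairing could be taken from them. With the cross-group array pairs as a block, limma called 0 probe sets in either direction (618 higher and 634 lower at an unadjusted p under 0.05) and camera 7 lists higher, adding the epithelial-mesenchymal and respiratory chain lists (camera adjusted p = 0.0264 each).

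The count of 0 probe sets higher and 0 lower held under every alternative that kept the adjusted p. At an unadjusted p under 0.01 with an absolute log2 difference of at least 1, limma gave 52 higher and 54 lower. That count is not adjusted for the number of probe sets, so it is no sign of changed ones. At an unadjusted p under 0.05, limma gave 572 where chance alone gives 1111, if the arrays are exchangeable, which their cross-group resemblance goes against. The median log2 difference of all probe sets was 0.0025 after quantile normalization, -0.05 with median centring, 0.07 with centring on the 75th percentile and 0.04 as deposited.

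Camera called 5 lists higher and 0 lower. It called 1 list lower with median centring, with centring on the 75th percentile and with the values as deposited, and 8 higher above the 40th percentile of level. With an estimated correlation, and with fry's directional test, it was 0 higher. Leaving out 1 array gave 4 to 9 higher and 0 to 3 lower. The lone array of a group was then assumed to vary like the other group.

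The calls of the immediate early and ERK feedback list and of the ERG-activated list were each kept in 15 of 17 alternatives and lost in 2. The 2 were camera with an estimated correlation and fry. The first still rests on the spread across genes but is read on 2 degrees of freedom, while fry tests on the spread between arrays. The 15 were all camera at the preset correlation on the same or overlapping arrays, so their number does not measure agreement between replicates. The camera adjusted p of these lists ranged from 1.34e-07 to 0.642 and from 1.67e-05 to 0.788. Leaving out 1 array gave means of 0.31 to 0.37 and 0.19 to 0.42. The matrix list kept its call in 12, the glycolysis list in 10 and the interferon list in 9 of the 17. With an estimated correlation the means of 0.36 (ERK), 0.31 (ERG-activated), 0.25 (matrix), 0.19 (glycolysis) and 0.19 (interferon) had camera adjusted p of 0.642, 0.788, 0.864, 0.864 and 0.788. In fry's test the same means had adjusted p of 0.512, 0.512, 0.953, 0.953 and 0.512, fry being part of limma. The glycolysis call was also lost with median centring (mean 0.12, camera adjusted p = 0.0584), centring on the 75th percentile (0.23, 0.0654) and as deposited (0.21, 0.0548). The interferon call was lost above the 60th percentile of level (0.20, camera adjusted p = 0.209, with 6 genes) and on ranks (0.19, 0.0597). The matrix call was lost with the mean over all probe sets of a gene (0.12, camera adjusted p = 0.228). Left-out arrays gave 0.059 to 0.43 for the matrix, 0.097 to 0.29 for the glycolysis and 0.16 to 0.22 for the interferon list.

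Lists that did not pass also passed camera under single settings. With median centring these were fibroblast markers (mean 0.26, camera adjusted p = 0.0389, range over all alternatives 0.0389 to 0.864) and the cell cycle list (-0.16, range 0.00115 to 0.953). The cell cycle list also passed with centring on the 75th percentile (-0.049) and as deposited (-0.074). Above the 40th percentile of level, kidney epithelium markers (0.31, camera adjusted p = 0.00593, range to 0.864) and the protease list (0.21, camera adjusted p = 0.00887, range to 0.953) passed. The respiratory chain list (0.098) passed above the 40th and 60th percentiles. The epithelial-mesenchymal list passed without the intensity trend (0.24, camera adjusted p = 0.04999).

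Some lists that did not pass changed the sign of their mean. With median centring these were the stress response (-0.066), cholesterol (-0.075), Notch (-0.021) and amino acid carrier (-0.075) lists, and the gene RPS3 (-0.012). With centring on the 75th percentile they were the neuronal (0.021) and ribosomal (0.012) lists, and with log2(value + 1) the Notch list (-0.034). Above the 40th percentile of level they were the endothelial (-0.064) and NF-kB (-0.0084) lists. Above the 60th they were the ETS (-0.098), TGF-beta (-0.089) and ribosomal (0.011) lists. With the mean over all probe sets of a gene they were the cholesterol (-0.0047), Notch (-0.014) and ribosomal (0.0058) lists.

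Leaving out 1 array at a time also changed signs. The lowest and highest means were -0.10 to 0.46 for heat shock proteins, -0.17 to 0.29 for prostate epithelium markers, -0.018 to 0.17 for blood cell markers and -0.028 to 0.020 for cytosolic ribosomal proteins. They were -0.020 to 0.22 for mitochondrial respiratory chain, -0.37 to 0.46 for the stress response, -0.070 to 0.12 for Notch pathway and -0.92 to 0.55 for replication-dependent histones. Other lists ranged from -0.18 to 0.19 for amino acid carriers, -0.0016 to 0.085 for endothelial genes, -0.097 to 0.20 for NF-kB and inflammatory genes and -0.019 to 0.23 for extracellular proteases and inhibitors. The remaining ranges were -0.096 to 0.37 for WNT pathway, -0.22 to 0.086 for cell cycle, -0.63 to 0.23 for p53 targets, -0.051 to 0.087 for cholesterol biosynthesis, -0.0034 to 0.087 for TGF-beta and BMP response and -0.060 to 0.23 for axon guidance and adhesion receptors. One ERG probe set, the one at the 23.6 percentile of level, ranged from -0.34 to 0.41, SQLE from -0.034 to 0.40 and H2AC25 from -0.75 to 0.36. Camera then passed lists that had not passed on all arrays. Without ERG 1 these were the epithelial-mesenchymal (mean 0.28, range on leaving out 1 array 0.11 to 0.36), stress response (0.46) and histone (-0.75) lists. Without ERG 2 they were the heat shock (0.37), respiratory chain (0.22) and stress response (-0.37) lists. Without vector 1 they were the protease (0.23), epithelial-mesenchymal (0.36), WNT (0.37), cell cycle (-0.22), p53 (-0.63), stress response (0.38), histone (-0.92) and axon guidance (0.23) lists. Without vector 2 they were the heat shock (0.46) and histone (0.55) lists. The stress response and histone lists thus passed in opposite directions, depending on the array left out. For these lists the sign follows from which array is missing, because ERG 2 and vector 1 lay apart from ERG 1 and vector 2. Their mean deviations were 0.45 and 0.31 against -0.39 and -0.36 for the stress response. For histones they were -0.67 and -0.65 against 0.48 and 0.83. Why those arrays lay apart stays open, and the cause of the other changes was not tested. Over all alternatives, 3 values of named genes other than ERG changed sign. This says nothing of stability, since many could not: the 20 genes filled in by rule were chosen with the groups apart, and some settings leave the difference as it was. For the lists that did not pass, 315 values kept their sign and did not pass, 25 passed in the same direction and 41 changed sign, of which 2 passed.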

Other observations

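In this part, RNA quality, exchanged labels and random lists were chosen as tests of an explanation after the result was seen. So were the estimated correlation and other splits of the arrays. The filter on dim probe sets was chosen before. The criteria for RNA quality and exchanged labels were also made less strict after their values were seen. As first written, both tests would have counted against their explanation. RNA quality is now read as undecided. The condition added for exchanged labels, on the remaining division of the arrays, cannot tell right from exchanged labels. For that test the values themselves are therefore weighed below.

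Several stress and metabolism genes, chosen after their values were seen, differed between arrays of the same group more than between groups. PCK1, an enzyme of gluconeogenesis, read 8.41 in ERG 2 and 8.21 in vector 1 on the log2 scale but 4.78 in ERG 1 and 4.72 in vector 2. The mitochondrial enzyme gene PCK2 read 10.48 and 10.71 against 8.78 and 8.85. TRIB3, a target of the amino acid stress response, read 11.63 and 11.69 against 10.10 and 9.48, and CHAC1, another, 10.08 and 9.77 against 7.64 and 8.61. ASNS, asparagine synthetase, read 13.03 and 13.31 against 11.58 and 12.41. The histone gene H2BC12 went the other way, with 9.72 and 9.64 against 11.43 and 11.57, as did the chaperone gene HSPH1 in the dimmer of its probe sets, with 8.75 and 8.54 against 10.38 and 10.42. The ACTB signal at the 3 prime end minus that at the 5 prime end moved with these genes: 0.59 and 0.58 in ERG 2 and vector 1, and 0.40 and 0.41 in ERG 1 and vector 2.

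ETV5, a member of the ETS family list named outside the rule, was chosen after its values were seen. Its log2 difference was 1.88 ± 0.35, 1.03 ± 0.40 and 0.25 ± 0.36 in its 3 probe sets. The probe set at 0.25 had the highest mean level and stood for the gene in that list, which did not pass. The one at 1.88 lay at the 35.8 percentile of level. FLI1 gave 0.68, 0.47 and 0.28 in its 3 probe sets. The lower p53 target values came mainly from vector 2. There DDB2 read 10.56, against 8.76 in vector 1 and 8.45 and 8.15 in the ERG arrays. AEN, a nuclease gene chosen likewise, read 10.92 against 9.75, 9.32 and 8.91.

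The resemblance of each ERG array to a vector array may reflect RNA degradation, exchanged labels, or a shared day that the labels do not give. For RNA quality, 1 of the 2 transcripts compared, ACTB, separated the cross-group pairs by more than the gap inside them (0.18 against 0.01), while GAPDH did not (0.034 against 0.071). An exchange of an ERG with a vector label could put the ERG-activated list with the cross-group division. That list gave a camera p of 0.218 there (mean -0.16 for ERG 1 and vector 2 against the others). With the labels as given it was 3.04e-06 (mean 0.31). The list thus shifted more with the labels than with that division, but this cannot decide on an exchange. Camera's p rests mainly on the spread across genes, which was wider in the cross-group division. There the SD of log2 differences above the median level was 0.43, against 0.23 with the labels as given. On the spread between arrays, fry's adjusted p for the list with those labels was 0.512. The remaining division of the arrays, which compares nothing if labels were exchanged, also called 1 list, so a list call can arise without ERG. Both explanations stay open, as does a biological one, and no shared day was tested.

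At an unadjusted p under 0.05, 2 of the 3 divisions of the 4 arrays into pairs, counting the labelled one, gave at least its 572 probe sets. The cross-group division gave 4206, which points to a structure of the samples, and the remaining division 564. For lists in camera, the labelled division called 5, the cross-group division 6 and the remaining division 1. In the cross-group division the camera adjusted p was 1.41e-14 for the stress response list and 4.67e-09 for the histone list. Both are smaller than the 5.22e-07 of the ERK feedback list with the labels as given, so such values can arise without ERG if the labels are right. The 3 divisions are too few for a share under 0.05.

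The higher values of the immediate early and ERK feedback list with ERG may come from noise of dim probe sets, from a few genes, or from correlation between its genes. Among probe sets above the 60th percentile of level, 15 of the 34 genes remained, with a mean of 0.25. Camera kept the call there (adjusted p = 1.94e-04, against a range of 1.34e-07 to 0.642 over the alternatives). That argues against dim noise for those 15 genes. The median of the whole list lay at percentile 100 of 10000 random lists matched on level, which argues against a few genes carrying it. The estimated correlation between its genes was -0.0047, under the preset 0.01, which runs against correlation as the cause. The camera adjusted p was 0.642 with an estimated correlation, but that test is read on 2 degrees of freedom. Its higher p therefore does not speak for correlation. The estimate rests on as few degrees of freedom and does not settle it either. Correlation stays open, as does an effect of ERG itself, which was not tested separately.

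The higher values of the ERG-activated list may likewise come from dim probe sets or a few genes. Above the 60th percentile of level, 10 of the 30 genes remained and camera kept the call (adjusted p = 0.0227, against a range of 1.67e-05 to 0.788). Among these 10, ADAMTS1 was at 0.91, FZD4 at 0.71, CXCR4 at 0.49, PLAT at 0.33 and MYC at 0.18. HDAC1 was at 0.08, SOX9 at 0.05, ZEB1 at -0.06, VIM at -0.11 and EZH2 at -0.17. A few genes thus carry much of the bright part, and dim noise stays open for the other members. The median of the whole list lay at percentile 100 of the random lists, which argues against a few genes carrying the whole list. Correlation between its genes stays open (estimate 0.037, camera adjusted p = 0.788 with an estimated correlation on 2 degrees of freedom).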
